A study of Ictalurus furcatus with 9 samples.

How the data were processed

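Skin of blue catfish (Ictalurus furcatus) exposed to the bacterium Aeromonas hydrophila was compared with skin of control fish on 9 Agilent two-colour oligonucleotide arrays, 3 each at 2 h, 12 h and 24 h after challenge. Per the labels' protocols, fish stood in the bacterial bath for 2 h and were then held in aquaria of 30 fish, and cDNA was made from 500 ng of RNA of each sample. Per the labels, each array carried infected skin in one channel and control skin of the same time in the other, which the control channel of replicate 3 at 24 h puts in doubt. Infected RNA was labelled in Cy5 on 7 arrays and in Cy3 on replicate 3 at 2 h and replicate 3 at 12 h. The 2 h arrays were on one slide, and the 12 h and 24 h arrays on another.

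Per the file headers, the authors' scanner files hold spot intensity values extracted with Agilent Feature Extraction 10.1.1.1, while the submitters' processing notes name version 9.5.3. The deposited intensity columns used were the mean and median signals of each spot in both channels and the median local background, none of them normalized. The deposited processed intensity was background-subtracted, detrended and dye-normalized by LOWESS with a smoothing factor of 0.25, per the file headers. On the typical spot, though not on every spot, the deposited log10 ratio is the log10 of processed Cy5 over processed Cy3 signal. The authors' value table is also on the log10 scale. Set against the scanner files it equalled that ratio on 7 arrays, and its negative to within 4.99e-06 on the 2 arrays with infected RNA in Cy3, so that scale and direction are known (infected over control). Its median is 0 on every array, and no further centring was found.

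The array has 52649 features, of which 1319 are controls, and 50979 probes of 60 bases with 49375 distinct sequences. The files name each probe by a contig, with a prefix blue on 21227 probes and channel on 29752, and 20525 contig names hold the word unknown. No probe name or contig matched the gene table given for the species (assembly Billie_1.0), and 0 probes matched any of the 24 gene lists fixed before the data were examined. The planned tests of gene list shifts, with camera and fry, therefore have no members and were not run. A search of translated probes for protein motifs was tried before any fit and dropped, because nearly every motif had too few hits to test.

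Ratios were computed in R 4.3.3 with limma 3.58.1. Mean signals were corrected with normexp (offset 50) and loess-normalized within each array, control and outlier spots had weight 0, spots of one probe were averaged, and every log2 ratio was turned to infected over control. No spot was saturated. Probes well above background in either channel on every array of at least 1 time were kept, 19006 in all (37.3%). The share of probes well above background was between 31.6% and 44.1% in Cy3 and between 10.3% and 21.9% in Cy5. The number of arrays limits the precision.

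Replicates 1 and 2 of each time were compared before they were averaged. Over pairs of kept probes with the same sequence, the SD per array of their difference was 0.164 at 2 h, 0.170 at 12 h and 0.191 at 24 h, against 0.183, 0.159 and 0.189 between spots of one sequence on one array. The differences did not repeat over the same-sequence probes (r = -0.034, 0.007 and 0.007), while those from replicate 3 did (r from 0.674 to 0.848). A second yardstick, 26 kept probes present in 10 copies, gave a squared difference per probe of 0.78 times the sampling noise at 2 h, but 3.24 at 12 h and 2.26 at 24 h, and at least 49.5 against replicate 3. By this yardstick only the 2 h pair lies within the noise. Replicates 1 and 2 of each time were counted as 1 sample, their mean, which leaves 2 samples per time and 6 in all. This departs from the design fixed beforehand, which had 9 separate arrays. It was chosen after the same-sequence comparison and after the numbers of probes passing with 9, 8 and 6 columns had been seen, so the counts of the planned fit stand beside those with 6 samples throughout.

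The linear model had a term for each time and one for dye orientation and was fitted with lmFit and eBayes. P-values were adjusted by Benjamini-Hochberg over the kept probes, with a threshold of 0.05. Times were tested against 0, against each other and as their mean. The labels do not say that the arrays came from separate fish, so p-values measure at most the spread between these samples. Replicate 3 of 2 h and of 12 h is also the dye-swapped array. The dye term therefore takes up the gap between the samples that both times share. SEs and p-values do not measure that shared gap, and the fit has 2 residual degrees of freedom. Tested on simulated data of 19006 probes with 2 samples per time, the 6-sample fit recovered 10.4% of 2-fold, 88.1% of 4-fold and 97.0% of 16-fold changes at 2 h. The shares were 6.0%, 89.6% and 100% at 12 h, and 0%, 68.7% and 100% at 24 h. Of 18806 unchanged probes it called 19 at 2 h, 8 at 12 h and 8 at 24 h. In 20 simulated sets with no change, it called at most 4 probes in any comparison. The simulation added spot noise to a sample spread that already held it. It also took all 6 samples as independent, without control RNA shared between times. The simulated shares and calls therefore need not hold for the real arrays.

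The rule fixed beforehand for named genes leaves out contig names, which would leave none. After the annotation had been seen it was replaced by the 2 probes of smallest p in each direction per comparison, of distinct sequence and, for a single time, of one sign on its 3 arrays. Signal levels are means of log2 values per channel after loess and Aquantile normalization, open to dye bias. A 2-fold ratio in both samples of a time is a description chosen after the fit, with no test. Alternatives were other background corrections, normalizations, filters, variance models, dye and replicate terms, the value table, and each array left out. Sequences of probes are not printed. Figures were drawn with matplotlib 3.10.9.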

Results

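The arrays measured, at 3 times after a bath challenge with Aeromonas hydrophila, the ratio of transcript levels in infected to control skin of blue catfish, a freshwater food fish. The comparisons ask which transcripts differ early after infection and how the difference moves with time. Each time had 3 arrays, counted as 2 samples: the mean of replicates 1 and 2, and replicate 3. Replicates 1 and 2 differed by less than or about the noise between spots of one sequence. By 26 probes present in 10 copies only the 2 h pair did: the squared difference was 0.78 times the sampling noise at 2 h, 3.24 at 12 h and 2.26 at 24 h. With only the 2 h pair averaged, 164 probes passed at 2 h, 15 at 12 h and 76 at 24 h, against 1, 0 and 0 with all pairs averaged. Of the probes on the array, 19006 were bright enough to test. The files give contig names and do not pair them with genes, so the items below are contigs.

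At 2 h, the contig channel_unknownk50_539715 was lower in infected skin, with a fitted log2 ratio of -3.32 ± 0.14 (SE, n = 2 samples; limma adjusted p = 0.0266). Its ratio was -2.38 in the mean of replicates 1 and 2 and -4.26 in replicate 3. The dye term takes up most of this gap, so the SE does not measure it. The contig was well above background on 3 of 3 control channels and on 1 of 3 infected channels. The size of the fall is thus uncertain, and the fitted value ran from -5.95 to -2.88 under the alternatives. The contig channel_unknownk60_681106 had a ratio of -3.25 ± 0.21, negative on 3 of 3 arrays, and did not pass (limma adjusted p = 0.0824). It passed under 9 alternatives and not under 20, among the 9 median spot signals (0.0442), Agilent processed signals (0.0223) and the authors' values (0.0154). The last 2 are nearly the same data, with a ratio of -5.057 in both. The 9 also include the fits that do not average all pairs. Under all alternatives its ratio ran from -5.057 to -2.87. The smallest p in the other direction belonged to blue_UN10665 at 2.40 ± 0.16 (limma adjusted p = 0.0824) and blue_UN05640 at 2.77 ± 0.21 (limma adjusted p = 0.119). Both had positive ratios on 3 of 3 arrays and did not pass, while with median spot signals both did (limma adjusted p = 0.0442). In the planned limma fit of 9 separate arrays all 4 contigs passed. The adjusted p was 1.08e-05 for channel_unknownk50_539715, 2.63e-05 for channel_unknownk60_681106 and blue_UN10665, and 3.04e-05 for blue_UN05640. That fit counts replicates 1 and 2 of 2 h, which agree within the noise, as separate samples, so these p-values are too small. The same holds for its other p-values below, as far as replicates 1 and 2 are copies. In blue_UN05640 the samples lay apart, at 3.92 in replicates 1 and 2 and 1.63 in replicate 3.

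Over all probes at 2 h, 69 were at least 2-fold higher in both samples and 38 at least 2-fold lower in both, where unrelated samples would give 10.5 and 8.1. Another 160 were at least 2-fold in opposite directions, against 22.8 for unrelated samples. For higher, lower and opposite, a normexp offset of 0 gave 324, 156 and 517, Agilent processed signals 625, 389 and 1581, and median centring 20, 27 and 4320. The ratios of the samples had a correlation across probes of 0.036, with infected RNA in Cy5 in one and in Cy3 in the other. Probes are not independent replicates. The limma fit with 6 samples passed 1 probe, channel_unknownk50_539715, and 2149 probes (11.3%) had an unadjusted p under 0.05. Simulated sets with no change gave 0 to 1 in the same fit, and the call was lost under 9 alternatives and kept under 20. With the 9 arrays kept apart as planned, 1405 probes passed, 867 higher and 538 lower. In simulated sets with no change but copied arrays, that fit called between 203 and 324. Without replicate 3 of 2 h, of 12 h or of 24 h, 0 probes passed, as without a dye term.

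At 12 h no contig passed in the limma fit with 6 samples. The smallest p among contigs lower on 3 of 3 arrays belonged to channel_unknownUN51153, with a log2 ratio of -1.28 ± 0.14 (SE, n = 2 samples; limma adjusted p = 0.987), and channel_Contig26678 at -1.67 ± 0.19 (limma adjusted p = 0.987). On the 9 arrays kept apart both passed (limma adjusted p = 0.00202). In channel_unknownUN51153 the samples read -1.53 and -1.02, and in channel_Contig26678 -0.66 and -2.68. Replicate 3 of 2 h, also with infected RNA in Cy3, read -2.7 in channel_Contig26678. The dye term thus takes up much of the gap in that contig, and its SE and p-values do not measure it. The size for channel_unknownUN51153 is uncertain, -2.28 to -1.13 under the alternatives, with infected skin well above background on 1 of 3 arrays. Among contigs higher on 3 of 3 arrays, channel_unknownUN13462 had 1.30 ± 0.23 and channel_UN07367 had 1.22 ± 0.26, each with a limma adjusted p of 0.987 (0.0282 and 0.0599 on the 9 arrays kept apart). Most of both ratios came from replicate 3, at 2.41 and 2.22, against 0.19 and 0.21 in replicates 1 and 2.

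The samples of 12 h shared 0 probes at least 2-fold higher and 10 at least 2-fold lower, while 71 were 2-fold in opposite directions, against 2.4, 2.5 and 5.0 for unrelated samples. A normexp offset of 0 gave 9, 37 and 249, Agilent processed signals 34, 166 and 1310, and median centring 0, 4 and 7969. Their correlation across probes was -0.226. The limma fit with 6 samples passed 0 probes, and 869 (4.57%) had an unadjusted p under 0.05. On 9 arrays kept apart 35 passed, 3 higher and 32 lower, below the 160 to 267 of the sets with no change but copied arrays. By the 10-copy probes the 12 h pair is no mere copy, so those sets cannot judge this count. Replicate 3 at 12 h, with infected RNA in Cy3, had correlations of -0.4, -0.395 and -0.357 with the 24 h arrays, which have it in Cy5. The labelled direction was kept, since the dye orientations differ and the authors' value table turns the same arrays. Labels and value table both come from the submitters, so their agreement is no independent check of the direction.

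At 24 h, the contig blue_unknownContig_551078 had the smallest p, with a fitted log2 ratio of 4.86 ± 0.34 (SE, n = 2 samples) that did not pass (limma adjusted p = 0.339). It passed in the planned fit of 9 separate arrays (9.09e-05), and in all under 12 alternatives and not under 17. Among the 12 were no dye term (0.0332), Agilent processed signals (0.0491) and the authors' values (0.0344). The last 2 are nearly the same data, with a ratio of 4.898 in both. The 12 also include the fits that do not average all pairs, the fit without replicate 3 at 24 h and the replicate block with dye term. In the fit without replicate 3 and in that block fit, the gap between the samples of 24 h does not enter the spread. The contig read 5.32 in replicates 1 and 2 and 4.74 in replicate 3, well above background in both channels on 3 of 3 arrays. Its fitted value ran from 2.74 to 5.43 under the alternatives. At 12 h it was not well above background in either channel, and at 2 h not in infected skin. The contig channel_unknownk60_681106, whose ratio was negative at 2 h, read 3.19 and 3.86 in the samples of 24 h (fitted 2.81 ± 0.25, limma adjusted p = 0.635, or 0.00141 on 9 separate arrays). The contigs of smallest p in the other direction were channel_unknownUN80946 at -1.69 ± 0.28 and channel_Contig26678 at -1.30 ± 0.24, each with a limma adjusted p of 0.961 (0.00593 and 0.00838 on 9 separate arrays). The measured ratios of channel_Contig26678 at 24 h were only -0.04 and -0.11, and its fitted value comes from the dye term estimated on the other times. Those of channel_unknownUN80946 were -1.61 and -0.77, so through the same dye term its fitted value lies beyond both. It ran from -3.16 to -1.13 under the alternatives, with infected skin well above background on 1 of 3 arrays.

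**Figure D1:**
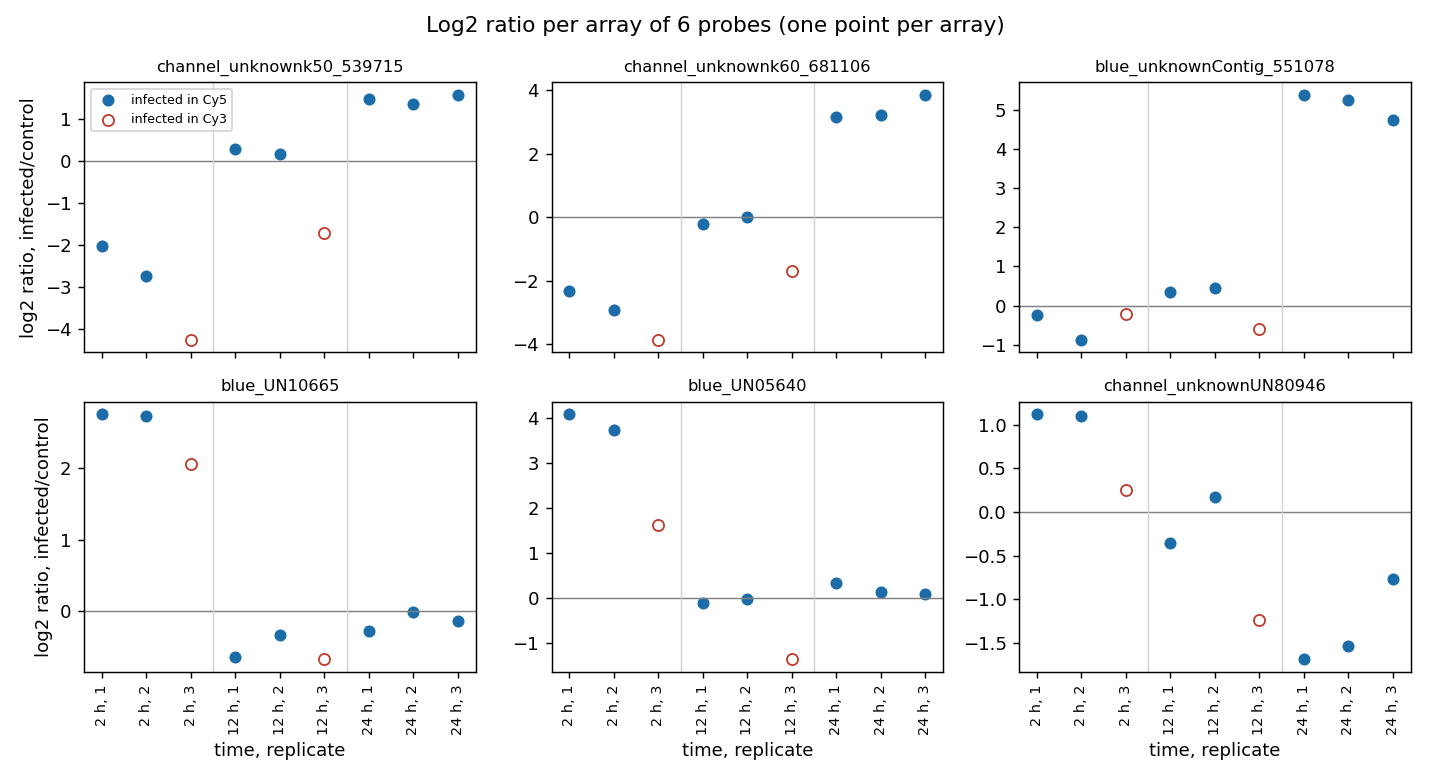
Log2 ratio of infected to control skin (vertical axis) on each of the 9 arrays (horizontal axis, time and replicate) for 6 contigs, with filled points for infected RNA in Cy5 and open points for Cy3. channel_unknownk60_681106 lies between -3.87 and -2.32 at 2 h and between 3.15 and 3.86 at 24 h. The 2 h and 12 h points of blue_unknownContig_551078 lie at background level in at least 1 channel.

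The samples of 24 h agreed more than those of the other times, with a correlation across probes of 0.459. In both, 219 probes were at least 2-fold higher and 13 at least 2-fold lower, against 15.1 and 1.7 for unrelated samples, and 15 were opposite. All 24 h arrays have infected RNA in Cy5, so a dye bias would count as agreement here. The control RNA of replicate 3 resembled that of 12 h (given below), so its ratio may be against 12 h control skin. The excess of higher over lower ratios turned under some settings. It was 369 higher and 512 lower with a normexp offset of 0, 469 and 1613 with Agilent processed signals, and 22 and 7230 with median centring. The excess stayed without background correction (199 and 8), with scaling between arrays (216 and 13) and with median spot signals (226 and 14). The limma fit with 6 samples passed 0 probes, and 774 (4.07%) had an unadjusted p under 0.05. A replicate block added to it gave 101 with the dye term and 13 without. With both terms the samples of 24 h are fitted exactly, so the gap between them does not enter the spread. The fit of 9 separate arrays passed 304 probes, 239 higher and 65 lower, within the 204 to 329 of sets with no change. Without replicate 3 at 24 h, 104 passed, from a single remaining sample of that time assumed to vary like the others, and Agilent processed signals gave 14.

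**Figure D2:**
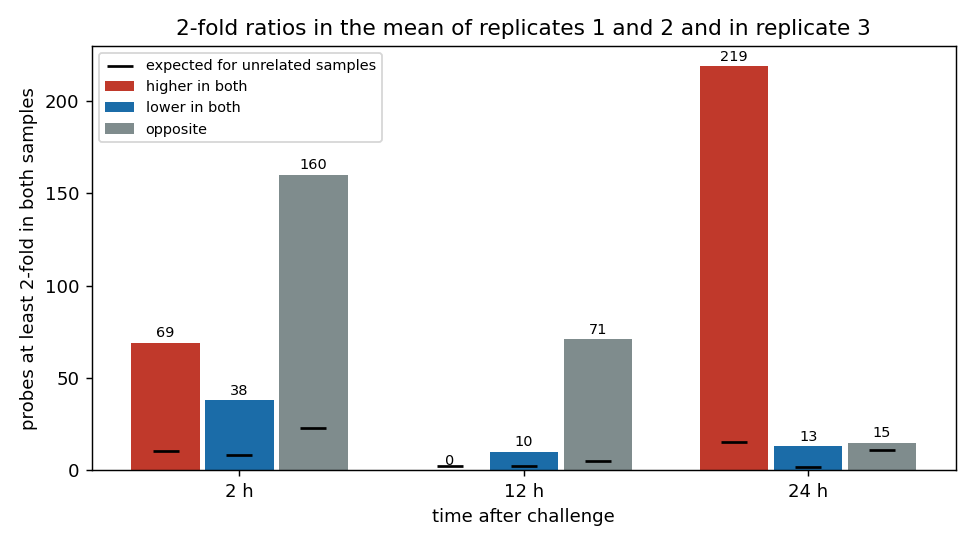
Number of probes (vertical axis) at least 2-fold from control in both samples of a time (horizontal axis), as bars for higher in both, lower in both and opposite, with a black line at the number expected for unrelated samples. At 24 h 219 probes were higher in both and 15 opposite, while at 2 h 69 were higher in both and 160 opposite.

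Between 2 h and 24 h, channel_unknownk60_681106 moved by 6.07 ± 0.33 on the log2 scale (SE, n = 2 samples per time; limma adjusted p = 0.0684) and channel_unknownk50_539715 by 3.85 ± 0.23 (limma adjusted p = 0.0684). Both sizes are uncertain, 4.72 to 8.49 for the former and 3.24 to 8.80 for the latter under the alternatives. At 2 h infected skin was well above background on 2 of 3 arrays for the former and on 1 of 3 for the latter. Both contigs were negative on all 3 arrays of 2 h and positive on all 3 of 24 h. The opposite course had its smallest p in blue_UN10665 at -2.77 ± 0.25 and blue_UN05640 at -3.51 ± 0.33, each with a limma adjusted p of 0.252. With 6 samples none of these passed, while on 9 separate arrays all 4 did (limma adjusted p = 8.95e-06, 5.12e-05, 0.000116 and 0.000116). channel_unknownk60_681106 passed under 13 alternatives and not under 16, and channel_unknownk50_539715 under 12 and not under 17. The passing alternatives include the fits that do not average all pairs. They also count the replicate block with dye term and the fit without replicate 3 at 24 h separately, which are the same fit for this contrast. From 2 h to 12 h, channel_unknownk50_539715 differed by 2.57 ± 0.20, blue_UN10665 by -2.99 ± 0.22 and blue_UN05640 by -3.50 ± 0.29 (limma adjusted p = 0.288 for each), and channel_unknownk60_681106 by 2.35 ± 0.29 (limma adjusted p = 0.653). On 9 separate arrays these had an adjusted p of 0.000822, 0.000117, 0.000117 and 0.0021. Mean log2 levels of channel_unknownk50_539715 at 2 h, 12 h and 24 h were 9.76, 7.05 and 6.04 in control skin. In infected skin they were 6.44, 6.30 and 7.52. Those of channel_unknownk60_681106 were 10.05, 6.99 and 6.79 in control and 6.79, 6.08 and 10.31 in infected skin. From 2 h to 12 h the measured levels of both thus moved mostly in control skin, while blue_UN10665 and blue_UN05640 moved more in infected skin. At 12 h infected skin was well above background on only 1 of 3 arrays for channel_unknownk50_539715 and for channel_unknownk60_681106, so a fall there could be hidden. These levels also come from different slides and mix the dyes.

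From 12 h to 24 h, channel_unknownk60_681106 differed by 3.72 ± 0.33 (SE, n = 2 samples per time; limma adjusted p = 0.575). The size is uncertain, 2.533 to 5.675 under the alternatives, and at 12 h infected skin was well above background on 1 of 3 arrays. blue_unknownContig_551078 also had a limma adjusted p of 0.575, but no difference is given, since at 12 h it was not well above background in either channel. In the other direction blue_UN06078 differed by -1.38 ± 0.25 and blue_UN02784 by -1.04 ± 0.23 (limma adjusted p = 0.999 for both). The fit of 9 separate arrays gave an adjusted p of 0.000622 for channel_unknownk60_681106, 0.000527 for blue_unknownContig_551078, 0.00725 for blue_UN06078 and 0.0351 for blue_UN02784. Ratios of blue_UN06078 were 1.11 and 1.05 in the samples of 2 h, 0.37 and 0.38 at 12 h, and -1.16 and -0.82 at 24 h.

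The limma fit with 6 samples passed 0 probes in each contrast between times. Without replicate 3 at 24 h it passed 39 for 24 h minus 2 h and 100 for 24 h minus 12 h, and with Agilent processed signals 7 and 9. An unadjusted p under 0.05 was reached by 1114 probes for 12 h minus 2 h, 1003 for 24 h minus 2 h and 568 for 24 h minus 12 h. For 9 arrays kept apart, the counts were 227 (27 higher, 200 lower), 556 (226 and 330) and 206 (199 and 7). Sets with no change gave 194 to 415, 393 to 597 and 354 to 541 in the same fit. The 2 h arrays had a slide of their own, so contrasts with 2 h cannot be told from slide, while 24 h and 12 h shared a slide. Control RNA of replicate 3 at 24 h may also be shared with 12 h (given below). Less surely, that of replicates 1 and 2 at 24 h may be shared with 2 h. For the latter, control differences repeated over same-sequence probes (r = 0.313 to 0.425, against at most 0.186 within replicates 1 and 2). With shared control RNA, the samples of 24 h minus 12 h and of 24 h minus 2 h would not be independent.

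On average over the 3 times, blue_UN07683 had a log2 ratio of 0.68 ± 0.10 (SE, n = 6 samples), positive on 9 of 9 arrays, and did not pass (limma adjusted p = 0.473). It was largest at 2 h, with 1.29 and 1.66 in the samples. blue_unknownContig_551078 had the same adjusted p, and no average is given, since it was measured in both channels on all arrays only at 24 h. The smallest p among negative averages belonged to channel_unknownk50_539715 at -1.18 ± 0.09 and channel_unknownContig_185343 at -1.16 ± 0.09 (limma adjusted p = 0.311 for both). On 9 separate arrays the adjusted p was 0.0103 for blue_UN07683, 0.00363 for blue_unknownContig_551078 and 0.00159 for these 2. The ratios of channel_unknownContig_185343 were -2.37 and -2.60 in replicate 3 of 2 h and 12 h, the arrays with infected RNA in Cy3, and between 0.09 and 0.25 in the other 4 samples. The dye term takes up this gap, so the SE does not measure it. Through that term channel_unknownContig_185343 had a fitted value of -1.11 at 24 h, where its samples read 0.12 and 0.25. The samples of channel_unknownk50_539715 at 24 h read 1.4 and 1.57, so its negative average is not a fall at every time. The limma fit with 6 samples passed 0 probes and 1864 had an unadjusted p under 0.05. It passed 24 without replicate 3 at 24 h and 32 with the replicate block and dye term. With 9 arrays kept apart 587 passed, 291 higher and 296 lower, against 42 to 129 in sets with no change but copied arrays.

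The level of control skin itself differed between arrays. Among the 7 arrays with control RNA in Cy3, control channels of replicates 1 and 2 of one time differed by a robust SD per array between 0.067 and 0.081 (log2, bright probes). Those of 2 h and 24 h, replicates 1 and 2, differed by 0.113 to 0.118, although they lay on different slides. The latter differences repeated over same-sequence probes with r of 0.313 to 0.425, against at most 0.186 within replicates 1 and 2 of one time. Control skin of replicate 3 at 24 h differed by 0.084 to 0.088 from the 12 h controls and by 0.554 to 0.556 from the other 24 h controls on its own slide. The 12 h controls differed by 0.579 to 0.583 from the 24 h controls of replicates 1 and 2. Infected skin of replicate 3 at 24 h differed by 0.265 to 0.275 from that of 12 h and by 0.387 to 0.394 from that of 24 h.

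**Figure D3:**
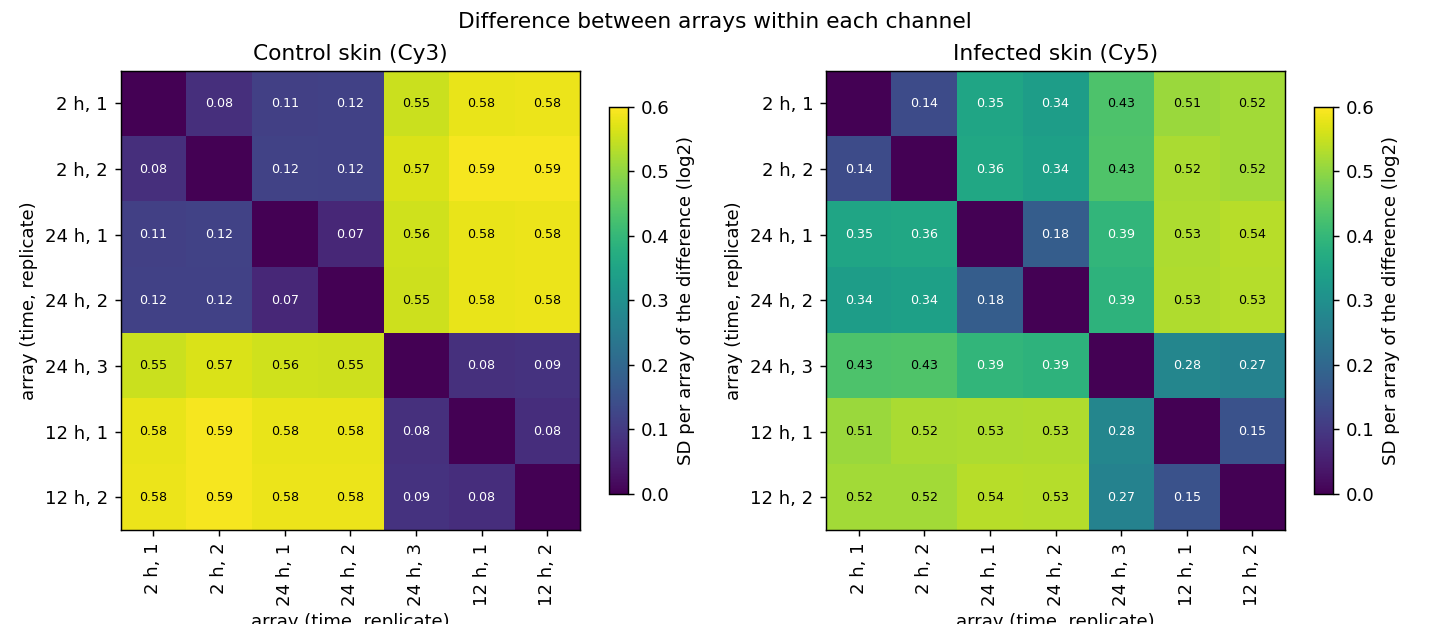
Robust SD per array of the log2 difference (colour and number) between each pair of the 7 arrays (both axes, time and replicate) with control RNA in Cy3, for control skin on the left and infected skin on the right. Control skin of replicate 3 at 24 h differs by at most 0.088 from the 12 h controls and by at least 0.554 from the other 24 h controls.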

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

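All tests of an explanation in this part were chosen after the results had been seen. In 10 named contigs well above background in both channels on at least 1 array of each of 2 times, every array of one time had a ratio on the other side of 0 from every array of the other time. Infected skin was so on only 1 of 3 arrays in channel_unknownk50_539715 at 2 h and in channel_unknownUN80946, channel_unknownUN13462 and channel_UN07367 at 24 h. blue_unknownContig_551078 also turned between 2 h and 24 h but is left out, since its infected skin was not well above background on any array of 2 h. The test of the difference itself, the limma contrast with 6 samples, missed the threshold for each. The planned contrast on 9 separate arrays passed for all but channel_unknownUN13462 (0.0596) and channel_UN07367 (0.183), with an adjusted p between 8.95e-06 (channel_unknownk60_681106) and 0.0351 (blue_UN02784). For 24 h minus 2 h the log2 differences were 9.04 in blue_unknownContig_813475 (adjusted p = 0.252), 6.07 in channel_unknownk60_681106 (0.0684), 3.85 in channel_unknownk50_539715 (0.0684), -2.38 in channel_unknownUN80946 (0.638) and -2.08 in blue_UN06078 (0.541). For 12 h minus 2 h they were -2.99 in blue_UN10665 and -3.50 in blue_UN05640 (0.288 for both). For 24 h minus 12 h they were -1.23 in channel_unknownUN13462, -0.94 in channel_UN07367 and -1.04 in blue_UN02784 (0.999 for each). In the fit with the dye term, channel_unknownUN13462 and channel_UN07367 had 24 h values of 0.07 and 0.28. By that fit these contigs do not turn, although their measured ratios do. blue_unknownContig_813475 was picked after its values were seen: its ratios were -3.53 and -5.86 in the samples of 2 h, and 4.95 and 6.93 at 24 h.

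The contigs that turned between 2 h and 24 h raise the possibility that RNA of bacteria on the skin was measured. Of 14 conserved stretches of bacterial ribosomal RNA searched on both strands, 5 were found, in 4 probes, all kept. Of the 7 probes at least 2-fold in both samples of 2 times in opposite directions, 3 held such a stretch: channel_unknownk50_539715, channel_unknownk60_681106 and blue_unknownContig_813475. The fourth is blue_unknownContig_551078. Some stretches were written from memory after the probe sequences had been read, and none of the 6 general primer or probe sites among them was found, so this search cannot decide for or against RNA of bacteria on the skin, and neither can the species of any bacterium be read from it.

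At 2 h and 12 h more probes were 2-fold in opposite directions in the samples than in one direction. At 2 h these were 160 against 107, which is the pattern itself and tests no explanation of it, so whether one response shared by both samples lies under part of the ratios stays open. The deviations of replicate 3 at 2 h and at 12 h had a correlation of 0.396 over all kept probes. The limit of 0.805 set by spot noise was taken over same-sequence kept probes only. These sets of probes differ, so the comparison cannot decide on a dye bias fixed to each probe as the whole cause. A dye bias, whole or partial, and a difference between the fish of replicate 3 and the others stay open. They were not separated, since replicate 3 is also the swapped array. Whether the dyes of these arrays were recorded rightly was not tested.

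Control skin of replicate 3 at 24 h lay with the control skin of 12 h. A further copy of the 12 h RNAs under a wrong label goes against the infected channel, which differed by at least 0.265, above the highest 0.178 within replicates 1 and 2. Differences of the infected channel repeated over same-sequence probes with r of at least 0.474, and those of the control channel with at most 0.194. This cannot decide on a labelling batch that moves both channels, since a difference of infected RNA between times would add to it. Infected skin of replicate 3 also differed less from 12 h (0.265 to 0.275) than from the other 24 h arrays (0.387 to 0.394). The same control RNA on the 3 arrays is in line with a control difference of at most 0.088, close to the 0.081 within replicates 1 and 2. Whether control fish of 12 h and 24 h were in fact shared is not given in the sources used here, and no biological explanation was tested.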

How the results depend on the processing

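The fit of 9 separate arrays with the dye term was the plan. Averaging replicates 1 and 2, the other fits of 9 arrays, averaging only the 2 h pair and all counts of 2-fold ratios were chosen after seeing the data. Counts are given in the order 2 h, 12 h, 24 h, 12 h minus 2 h, 24 h minus 2 h, 24 h minus 12 h and average, and a count left out equals that with 6 samples (1 at 2 h, otherwise 0). With 9 arrays kept apart they were 1405, 35, 304, 227, 556, 206 and 587. On 9 arrays without the dye term they were 615 at 2 h, 557 at 24 h, 46, 320, 186 and 705 in the contrasts and average, and 0 at 12 h. With only the 2 h pair averaged they were 164, 15, 76, 24, 72, 75 and 77. With the pair as a random block (correlation 0.527) they were 734, 23, 126, 57, 188, 103 and 171. Simulated sets with no change, where copies counted as samples, gave 267 calls at 2 h in the median set. They also gave 160 to 267 at 12 h and 354 to 541 for 24 h minus 12 h, more than the data, so they do not show the cause.

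With 6 samples, the counts stayed under 30 in all planned settings except the replicate block and the fit without replicate 3 at 24 h. Agilent processed signals gave 3 at 2 h, 14 at 24 h, 7 for 24 h minus 2 h and 9 for 24 h minus 12 h, and the authors' values gave 3, 25, 8 and 11. Trend and robust eBayes gave 4 at 2 h, 2 at 24 h, 1 for 12 h minus 2 h, 4 for 24 h minus 2 h, 2 for 24 h minus 12 h and 1 on average. Median spot signals gave 4 at 2 h and 2 for 24 h minus 2 h, and no filter gave 2 for 24 h minus 2 h. The count at 2 h was 0 without background correction, with median centring, with the strict filter (3758 probes), and without a dye term or on arrays of that time alone, where 24 h gave 1. The cause was not tested. Scaling between arrays, a normexp offset of 0, array weights and leaving out saturated spots (none) changed no count by over 1.5 times, nor did a 1.5-fold threshold. No array direction was turned, as the labels and the authors' values agree on it, though both come from the submitters. The lowest correlation between single arrays of a time was -0.208.

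Leaving out 1 array at a time, counts ranged from 0 to 1 at 2 h, 0 to 104 at 24 h, 0 to 39 for 24 h minus 2 h, 0 to 100 for 24 h minus 12 h and 0 to 24 on average, and were 0 for 12 h and 12 h minus 2 h. The values 104, 39, 100 and 24 all came without replicate 3 at 24 h. Numbers of probes 2-fold in both samples were not taken without replicate 3 of the time itself, which leaves 1 sample. With each other array left out, they ranged from 65 to 73 higher, 38 to 41 lower and 155 to 160 opposite at 2 h. They ranged from 0 to 1, 10 to 13 and 71 to 73 at 12 h, and from 217 to 221, 12 to 14 and 15 to 17 at 24 h.

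Replicate numbers were not taken to pair the arrays: deviations of arrays with one number correlated across probes between 0.062 and 0.396, not above 0.1 throughout. With the replicate block and dye term the counts were 0 at 2 h, 101 at 24 h, 39 for 24 h minus 2 h, 100 for 24 h minus 12 h and 32 on average. For contrasts between times that fit is the same as the one without replicate 3 at 24 h, so they are not separate checks. With the replicate block and no dye term the counts were 0, 13, 1, 2 and 1. The replicate block and dye term on 9 arrays kept apart gave 2086, 32, 1387, 556, 1082, 1276 and 1627.

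Numbers of 2-fold ratios depended on how low signals were treated. For higher, lower and opposite, Agilent processed signals gave 625, 389 and 1581 at 2 h, 34, 166 and 1310 at 12 h, and 469, 1613 and 291 at 24 h. The authors' values gave 625, 314 and 1554, then 34, 166 and 1307, then 468, 1613 and 289. A normexp offset of 0 gave 324, 156 and 517, then 9, 37 and 249, then 369, 512 and 131. Median centring gave 20 higher and 4320 opposite at 2 h, 4 lower and 7969 opposite at 12 h, and 22, 7230 and 32 at 24 h. It left the median kept probe of an array between -1.25 and 0.98, against -0.07 to 0.07 with loess, and the processed signals between -0.63 and 0.42. No background correction gave 45 higher and 25 lower at 2 h, and 8 lower and 8 opposite at 24 h. The strict filter gave 45 and 23 at 2 h, 6 lower at 12 h, and 7 lower and 9 opposite at 24 h.

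Of 905 values of named contigs under alternatives, 715 kept their direction and side of the threshold, 180 newly passed, 9 no longer passed and 1 turned. The 9 all belong to channel_unknownk50_539715 at 2 h, whose ratio ranged from -5.95 to -2.88 and its adjusted p from 1.08e-05 to 0.818. The one that turned is channel_Contig26678 at 24 h, 0.20 with the replicate block and no dye term. In Cy5 at most 21.9% of probes were well above background on any array.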

Other observations

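All tests in this part were chosen after the results had been seen, except those of other splits, which were planned. A larger share of the contigs with the prefix blue than of those with the prefix channel was 2-fold higher in both samples of 24 h. The shares were 100 of 6851 (1.46%) and 119 of 12155 (0.98%), with an odds ratio of 1.50 (Fisher's exact test, two-sided, p = 0.00362, adjusted p = 0.0187 over 6 tests). At 2 h the prefixes did not separate among higher probes (0.39% and 0.35%, adjusted p = 0.616). Contigs with unknown in their name were fewer among probes 2-fold higher at 2 h, 16 of 7467 (0.21%) against 53 of 11539 (0.46%), with an odds ratio of 0.47 (adjusted p = 0.0187). They did not separate among probes higher at 24 h (1.02% and 1.24%, adjusted p = 0.248) or lower at 2 h (0.23% and 0.18%, adjusted p = 0.611). Among probes lower at 2 h, blue contigs were 0.29% and channel contigs 0.15% (adjusted p = 0.083). Probes are not independent, and several can share a contig's transcript, so these p-values are too small.

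The dye term was large for single probes: its median absolute value was 0.133 and its 95th percentile 0.534 on the log2 scale. With 6 samples 0 probes passed for it by limma, and 2602 had an unadjusted p under 0.05. With 9 arrays kept apart 1954 passed.

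For the average over the 3 times the real count was 0, which all 32 of the 32 splits by turned signs of the 6 samples reach by definition, so the splits say nothing about chance there. The highest other split gave 133, in the split that turns both Cy3 arrays, where the dye term cannot be estimated. With 9 arrays kept apart, 6 arrays make only 10 splits for a contrast, too few for a share under 0.05. The real split gave 227 probes for 12 h minus 2 h, where 1 of the 10 splits gave as many and the highest other gave 13. It gave 556 for 24 h minus 2 h (1 of 10, highest other 302) and 206 for 24 h minus 12 h (2 of 10). There the highest other gave 768, several times the real count. It sets replicates 1 and 2 of 12 h with replicate 3 of 24 h, the arrays with like control skin. It also keeps replicates 1 and 2 of each time together, as do the highest other splits of the other contrasts. The cause of its count was not tested.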
